A study of Mus musculus with 44 samples.

How the data were processed

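Small RNA was sequenced from mouse cells and tissues in 44 libraries of 40 cell types or tissues. The labels put 10 types in the B lineage, 10 in the T lineage and 5 in the myeloid lineage. They add natural killer cells, hematopoietic progenitors, embryonic stem cells, embryonic fibroblasts and 11 tissues. Mature B cells, LPS plus IL-4 stimulated B cells and neutrophils had 2, 3 and 2 libraries, and the other 37 types had 1 library each. The labels number these replicates without saying that each came from its own animals, and the series text speaks of both biological and technical replicates. The p-values of the replicated comparisons thus measure the spread between these libraries, which may be technical. Per the labels' protocols, total RNA was isolated with Trizol and libraries were made with the Illumina small RNA protocol. Reads were aligned with Bowtie 0.9.9.3, per the submitters' processing notes, and the genome build is not given in the sources used here.

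Each deposited file lists 3214 features as tags per 1000000 miRNA tags (RPM), per the file headers. Of these, 785 are known miRNA arms and 2429 are candidate hairpin arms that the files name by a running number and chromosome. Names such as mmu-mir-148a_3p were rewritten as miR-148a-3p. Feature values of each library summed to 1000000 RPM, so only relative abundance is measured. Low values were whole multiples of the value of 1 tag, and between 96.4% and 98.6% of the non-zero values of a library came out as whole tags within a tolerance of 0.001. The recovered depth ran from 448661 to 11553551 tags with a median of 3938250. For 46 features the tags were split between near-identical miRNAs in at least 1 library, and the shares of such members are uncertain. Among them were miR-27a and miR-27b, miR-23a and miR-23b, and let-7a and let-7c. Values that were not whole tags held 0.88% to 48.0% of the tags of a library. They held 2.82% and 22.6% in mature B replicates 1 and 2, and 21.7%, 3.55% and 4.38% in stimulated B replicates 1, 2 and 3. Replicates differed by more than counting noise, with chi-square per degree of freedom from 98.1 to 1887, which does not tell biological from technical replicates. Each library was used as a sample of its own.

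The designs were fixed before the data were examined, as were the 33 miRNA lists (families, genomic clusters, and markers of other cell types and tissues) and the rule for named miRNAs. They foresaw edgeR on counts, or limma if the files held no counts. Since the deposited values are RPM, each comparison was tested with limma 3.58.1 (R 4.3.3) on log2(RPM + 1) after TMM scaling, with trended and robust empirical Bayes variances. Features needed 10 RPM in at least as many libraries or types as the smaller group holds. Adjusted p-values are Benjamini-Hochberg values over the features tested, the tests are two-sided, and a feature was called at 0.05. Fold changes are on the log2(RPM + 1) scale, which understates the change of features near 0, and are given ± SE. The libraries of mature B cells, LPS plus IL-4 stimulated B cells and neutrophils were fitted together. The SE and p-values of each replicated comparison thus also rest on the spread within the third group. In comparisons over cell types the tags of a type's replicates were summed first, and the spread is that between types. Means in RPM are before TMM scaling. The shift that TMM scaling takes out of each log2 fold change is given with each comparison of 2 groups.

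The rule named the features with the largest changes among those called and at a mean of 50 RPM or more in the higher group. These were 10 per direction for the replicated groups, whose libraries also had to be separate, and 8 per direction for the comparisons over types. It added all tested members of the miR-17~92, miR-181, let-7, miR-221/222, miR-146 and single immune miRNA lists. A list member is counted by the arm with more reads over all libraries, which is the 3p arm for miR-17 and miR-150. Features merged from different miRNAs could not be list members. The lists thus do not hold miR-199a/199b-3p or miR-465a/465b/465c-3p, and count these miRNAs by other features. Lists with 3 or more tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. These tests used the limma log2 values, not the voom values foreseen, in 134 tests with adjustment over the lists of a comparison. For single libraries the rule named the most abundant feature and up to 3 features of at least 100 RPM with the largest ratio of RPM + 1 to the median of the other types of the lineage, of the other tissues, or of all other types. Their intervals are 95% exact Poisson intervals for RPM and exact Clopper-Pearson intervals for shares, and cover counting error only. A list in a single library was placed by the percentile of its median ratio among 10000 random lists matched on mean expression. The lists were fixed, but the pairs of library and list reported were chosen after the values were seen. No p-value was computed for single libraries.

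Alternatives were edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the recovered tags, other scalings, filters and pseudocounts, the replicate number as a block, and leaving out libraries or types. edgeR on recovered tags, the other pseudocounts, a covariate for the axis of replicate differences, and some omissions of single types or tissues were chosen after seeing the data. The fits were tested on simulated data in which 200 features were changed 2-, 4- or 8-fold. Shares are of the changed features that passed the filter. At 8-fold the recovered share ran from 56.3% (cultured against sorted T types) to 100% (activated against mature B cells) in comparisons of 2 groups, and it was 28.8% for the test of a difference between lineages. At 4-fold it ran from 22.7% (myeloid against lymphoid types) to 69.2% (neutrophils against mature B cells), and was 2.2% for that difference. At 2-fold it ran from 6.5% (B against T lineage) to 28.1% (neutrophils against mature B cells), and was 2.4% for that difference. Hairpin positions are those of GENCODE M21 (GRCm38), looked up by gene symbol. Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1 was used for the rest.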

Results

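Small RNA profiles of 27 blood cell types, 11 tissues, embryonic stem cells and embryonic fibroblasts of the mouse were compared to ask how miRNA abundance differs between lineages, stages and states of lymphocytes. Of the 3214 features, 376 reached 100 RPM in at least 1 library, and 351 of these were known miRNA arms. Known miRNAs took between 97.9% and 99.99% of the tags of a library. let-7f-5p, a member of the let-7 family found in most differentiated cells, was the most abundant feature in 35 of the 44 libraries. Depth was lowest in testes (448661 tags) and highest in follicular helper T cells (11553551 tags), where 3 tags stood for 6.69 and 0.260 RPM. Between replicates, 95% of the features at 100 RPM or more differed by less than 1.59-fold in neutrophils and 3.75-fold in mature B cells. In LPS plus IL-4 stimulated B cells this bound was 1.69-fold for replicates 2 and 3, and 7.16-fold and 6.13-fold for replicate 1 against replicates 2 and 3.

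Splenic B cells cultured for 72 hours with LPS and IL-4, which drive B cell proliferation and class switching, were compared with sorted mature B cells of the spleen. Culture and stimulation cannot be told apart here. In the stimulated cells (n = 3 libraries against 2), miR-148a-3p rose by 6.08 ± 0.62 on the log2 scale (adjusted p = 3.1e-05), from 12.5 ± 8.74 to 1536 ± 968 RPM (SD). miR-152-3p, which shares its seed, rose by 5.35 ± 0.58. miR-155-5p, processed from the Mir155hg transcript and needed for germinal center responses, rose by 3.86 ± 0.44, from 167 ± 24.8 to 3836 ± 440 RPM, and its 3p arm by 4.81 ± 0.43. miR-21-5p, abundant in many activated and transformed cells, rose by 3.32 ± 0.45 to 54941 ± 22508 RPM. miR-34a-5p, a p53 target, and miR-210-3p, a hypoxia-induced miRNA, rose by 5.72 ± 0.72 and 3.92 ± 0.76. In the opposite direction, miR-26a-5p fell by 3.70 ± 0.44, from 6342 ± 647 to 765 ± 63.2 RPM. miR-455-3p fell by 5.24 ± 0.54, and let-7b-5p and let-7c-5p fell by 3.40 ± 0.65 and 3.33 ± 0.56. The tags of let-7c-5p were split between near-identical miRNAs in 30 libraries.

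**Figure D1:**
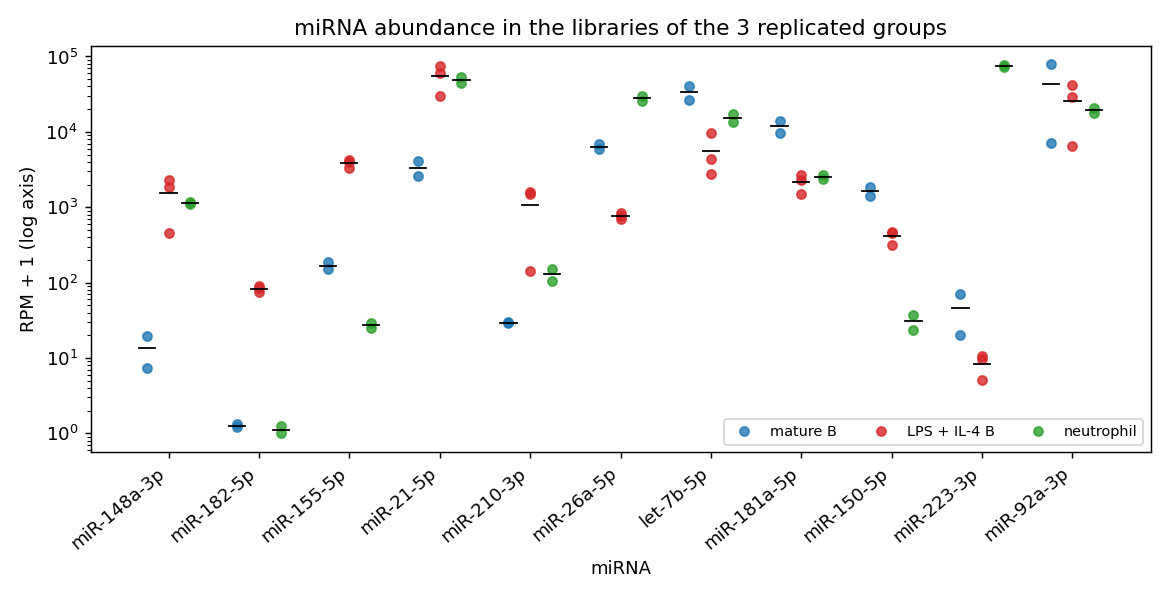
Abundance of 11 miRNAs in each library of mature B cells (2), LPS plus IL-4 stimulated B cells (3) and neutrophils (2), as RPM + 1 on a log axis. Points are libraries and bars are group means, with miR-155-5p at a mean of 3836 RPM in the stimulated B cells and miR-223-3p at 74747 RPM in neutrophils, while miR-92a-3p differs widely between the 2 mature B libraries.

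By family, miR-181a, miR-181b and miR-181c fell, and miR-181d did not pass the test. miR-181a-5p, which tunes antigen receptor signaling in developing lymphocytes, fell by 3.13 ± 0.43. Adjusted over the list alone, all 4 members fell. Of the miR-17~92 cluster, which promotes lymphocyte survival and proliferation, 3 of 5 tested members rose, with values of 2.89 ± 0.48 for miR-18a-5p, 2.38 ± 0.49 for miR-20a-5p and 3.29 ± 0.46 for miR-19b-3p, and the count adjusted over the list alone was also 3. miR-92a-3p of the same cluster was at -0.91 ± 0.88 (adjusted p = 0.41). Its value was -2.67 without mature B replicate 1, which passed the test, and 0.84 without mature B replicate 2. All 3 members of the cluster of miR-182, miR-96 and miR-183 rose, led by miR-182-5p (5.73 ± 0.49), and all 4 tested members of the Sfmbt2 intronic cluster rose. The 4 tested epithelial markers (miR-200a, miR-200b, miR-200c and miR-203, abundant in epithelia) fell. The counts adjusted over these lists alone were the same. These 3 lists and the miR-181 family passed camera at the preset correlation (adjusted p = 0.033, 0.033, 0.033 and 0.050), and none passed with an estimated correlation (adjusted p = 0.80, 0.81, 0.83 and 0.81). fry, which asks whether the members of a list moved one way on balance, called these 4 (adjusted p = 0.00096, 0.011, 0.011 and 0.0061). It also called the miR-17~92 cluster (adjusted p = 0.023) and the cluster from miR-106a to miR-363 (adjusted p = 0.011), whose 3 tested members all rose. Of the let-7 family 1 of 9 members rose (miR-98-5p, 2.16 ± 0.50) and 2 fell, and the same members were counted over the list alone. Of 10 single immune miRNAs 4 rose and 5 fell, among the latter miR-150-3p (-2.29 ± 0.54), an arm of a miRNA of resting lymphocytes that represses Myb. With library totals only, 3 of these 5 were not called (miR-150-3p at -1.63, miR-342-3p at -0.63 and miR-326-3p at -1.52). miR-221-3p (-0.10 ± 0.48), miR-222-3p (1.33 ± 0.52) and miR-146a-5p (-0.06 ± 0.48) did not pass.

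In all, 162 of 305 features were called, 85 higher and 77 lower, and 75 higher and 42 lower without mature B replicate 2. Lower calls were the more numerous without mature B replicate 1 (76 to 81) or stimulated replicate 1 (95 to 100) or 3 (60 to 68). TMM scaling took a shift of 0.65 out of the log2 fold changes, and with library totals only the split was 105 higher and 46 lower. With the neutrophil libraries left out of the fit, 139 of 255 features were called, 77 higher and 62 lower. The call of miR-181b-5p (-1.77 ± 0.47) was lost without mature B replicate 2 (-1.41). That of miR-342-3p (-1.29 ± 0.45) was lost without mature B replicate 2 (-0.99) or stimulated replicate 2 (-1.06) or 3 (-1.30) and with the replicate number as a block (-1.30), and that of miR-326-3p (-2.02 ± 0.62) without mature B replicate 1 (-1.11) or stimulated replicate 2 (-1.78). These 2, let-7b-5p, let-7c-5p, miR-96-5p and miR-150-3p were among those that lost theirs in a fit over all 44 libraries (-0.86, -1.56, -2.97, -2.91, 4.11 and -1.86).

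Peritoneal neutrophils, 88% pure per the labels, were compared with mature B cells (n = 2 and 2). miR-223-3p, a regulator of granulocyte maturation encoded on chromosome X (GRCm38 96242817 to 96242926), was at 74747 ± 3991 RPM in neutrophils and 44.5 ± 35.7 RPM in mature B cells (10.33 ± 0.61, adjusted p = 6.6e-07). miR-147-3p, induced by Toll-like receptor signaling in myeloid cells, was higher by 7.08 ± 0.49, miR-135a-1-3p by 7.36 ± 0.53, miR-129-5p by 6.42 ± 0.68, miR-338-3p by 6.38 ± 0.50 and miR-148a-3p by 5.98 ± 0.67. miR-21-5p and miR-222-3p were higher by 3.28 ± 0.49 and 3.45 ± 0.58. Both arms of miR-150 were lower, with miR-150-5p at 29.6 ± 9.53 against 1630 ± 308 RPM (-6.38 ± 0.51). miR-455-3p (-6.87 ± 0.59), miR-342-3p (-4.83 ± 0.50), miR-181a-5p (-2.86 ± 0.47), miR-146a-5p (-2.34 ± 0.52) and miR-155-5p (-3.26 ± 0.48) were lower too.

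Of the single immune miRNAs 4 of 10 were higher and 4 lower in neutrophils, and the same numbers were counted over the list alone. Of the miR-181 family 2 of 4 members were lower, and of the let-7 family 2 were higher and 2 lower, again with the same counts over each list alone. All 4 Sfmbt2 cluster members and all 3 tested kidney markers (miR-192, miR-194 and miR-30a) were higher, and the 3 tested members of the cluster from miR-106a to miR-363 were lower. None of the 17 lists passed camera at either correlation. fry called 6 lists. They were the cluster from miR-106a to miR-363, the miR-181 family, the miR-99/100 and miR-125 group, and the kidney, brain and Sfmbt2 lists (adjusted p = 0.0056, 0.024, 0.012, 0.0056, 0.0056 and 0.0093). Of the brain markers 2 of 4 were higher and 1 lower, and of the liver markers 2 of 3 were higher. The test called 148 of 305 features, 89 higher and 59 lower, after a TMM shift of 0.63, and with library totals only the split was 113 to 45. With the stimulated B libraries left out of the fit, 168 of 247 features were called, 112 higher and 56 lower. The balance rested on single libraries, with 47 higher and 57 lower without neutrophil replicate 1 and 78 higher and 37 lower without neutrophil replicate 2. Without neutrophil replicate 1, the calls of miR-18a-5p (2.19 ± 0.53), miR-19b-3p (2.08 ± 0.51) and let-7e-5p (1.90 ± 0.50) were lost, with values of 1.47, 1.43 and 1.21, and so were those of let-7f-5p (-1.73 ± 0.52), miR-98-5p (1.52 ± 0.55) and miR-142-5p (-1.52 ± 0.53), with -2.12, 0.99 and -1.83. The last 3 were also lost without neutrophil replicate 2 (-1.64, 1.75 and -1.51), as was miR-17-3p (-1.56 ± 0.49, there -1.13). miR-17-3p and miR-98-5p also lost their calls with the replicate number as a block (-1.56 and 1.52). Further losses came without mature B replicate 1 (let-7f-5p -1.39, miR-98-5p 0.80) or 2 (miR-142-5p -1.15, miR-17-3p -1.42), with library totals (miR-142-5p -0.89, miR-17-3p -0.93), with RLE scaling (let-7f-5p -1.56) and with edgeR on recovered tags (miR-98-5p 1.37). The fit over all 44 libraries ended the calls of let-7f-5p (-1.30), miR-142-5p (-1.09) and miR-17-3p (-1.13), and testing with no filter those of miR-17-3p, miR-98-5p and miR-142-5p.

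The stimulated B cells were next set as 3 types (LPS plus IL-4, LPS plus anti-IgD dextran, and LPS plus IL-4 on BclXL transgenic cells, labeled BalbC) against 4 sorted peripheral types (immature, mature, marginal zone and B1 cells). All 3 stimulated types were cultured, so culture and stimulation cannot be told apart. The BclXL type also brings in its strain and transgene. miR-148a-3p was again higher, at 1759 ± 1363 against 34.0 ± 33.6 RPM (5.28 ± 0.97, adjusted p = 0.0042, 3 of 3 types above the resting median). miR-155-5p was higher by 3.81 ± 0.78, miR-155-3p by 3.92 ± 0.79, miR-21-3p by 4.50 ± 0.84 and miR-210-3p by 3.52 ± 0.66. Lower were miR-181a-5p (2715 ± 582 against 15389 ± 6112 RPM, -3.30 ± 0.43), let-7c-5p (-3.09 ± 0.36), let-7b-5p (-3.28 ± 0.46), miR-26a-5p (-3.22 ± 0.59) and miR-203-3p (-4.23 ± 0.85). Of the let-7 family 3 of 9 members were lower, or 4 adjusted over the list alone. The tags of let-7a-5p and let-7c-5p were each split between near-identical miRNAs in 30 libraries. The call of let-7a-5p (-1.37 ± 0.35) was lost with RLE scaling (-1.17), library totals (-0.52), no filter on low values (-1.37) or the covariate for the axis of replicate differences (-0.87), and without the BclXL type (-1.08). Of the miR-181 family 1 of 4, or 2 over the list alone. Of the miR-17~92 cluster 2 of 5 members were higher, or 3 over the list alone. Both calls, of miR-18a-5p (2.21 ± 0.65) and miR-20a-5p (2.08 ± 0.55), were lost without the LPS plus IL-4 type (1.98 and 1.87), without mature B cells (1.91 and 1.91), with no filter on low values and with the axis covariate (1.82 and 2.00). That of miR-18a-5p was also lost without BclXL (2.06), marginal zone (1.93) or B1 cells (2.22), and that of miR-20a-5p without the anti-IgD type (2.02). Of the single immune miRNAs 3 of 8 were higher and 1 lower in both counts. Of the epithelial markers 2 of 4 were lower, or 3 over the list alone. Of the Sfmbt2 cluster 2 of 3 members were higher, or 3 over the list alone. None of the 14 lists passed camera at either correlation. fry called 4, the miR-17~92 cluster, the let-7 and miR-181 families and the epithelial markers (adjusted p = 0.032, 0.032, 0.033 and 0.032).

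In this comparison 37 of 211 features were called, 23 higher and 14 lower, after a TMM shift of 0.86, and with library totals only the split was 39 to 8. The balance turned with DESeq2 (31 higher and 43 lower), with the covariate for the axis of replicate differences (10 and 16) and without marginal zone B cells (24 and 26). The count was 21 without the LPS plus IL-4 type (11 higher and 10 lower), 24 without the BclXL type (17 and 7), 23 without mature B cells (13 and 10) and 34 without the anti-IgD type (25 and 9). miR-182-5p (3.71 ± 0.78) lost its call without the LPS plus IL-4 type (3.17), and miR-21-5p (2.88 ± 0.68) without that type (2.68), the BclXL type (2.98) or mature B cells (2.65). Those of miR-148a-3p (3.83), miR-182-5p (3.52), miR-21-5p (2.58) and miR-203-3p (-3.89) ended with a covariate for the axis of replicate differences.

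The B and T lineages were compared over 10 types each. miR-31-5p was at 5.47 ± 10.8 RPM in B types and 580 ± 1333 RPM in T types (-5.15 ± 0.89, adjusted p = 7.2e-04), with all 10 T types above the median of the B types. Of the miR-232724 clusters, whose members restrain several T helper programs, 4 of 5 members were lower in B types, or 5 adjusted over the list alone. miR-27b-3p was at 760 ± 483 against 5549 ± 3976 RPM (-2.73 ± 0.46), with miR-27a-3p at -2.68 ± 0.62, miR-23b-3p at -1.92 ± 0.38 and miR-23a-3p at -1.67 ± 0.52, though the tags of these pairs were split between near-identical copies in 42 libraries for miR-23a and miR-23b and in 44 for miR-27a and miR-27b. The list passed camera (adjusted p = 9.9e-06), but not with an estimated correlation (adjusted p = 0.13). Higher in B types were miR-191-5p (37522 ± 15162 against 13161 ± 3835 RPM, 1.53 ± 0.31) and miR-425-5p (1.30 ± 0.40), which come from a common host transcript, and miR-374-5p (1.65 ± 0.43) and miR-421-3p (1.39 ± 0.43). let-7e-5p (-1.98 ± 0.53) was the 1 called let-7 member, in both counts. Of the Sfmbt2 cluster 2 of 4 members were lower, or 4 over the list alone, and that list passed camera (adjusted p = 0.0051) but not with an estimated correlation (adjusted p = 0.51). No member of the miR-17~92 and miR-181 lists or of the single immune miRNAs was called by limma in either count.

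Over all features 17 of 191 were called, 5 higher and 12 lower in B types. The TMM shift was -0.10. The split was 3 to 10 without CD8 T cells and 3 to 11 without follicular helper T cells. It was nearer to even without other strains, the plasma cell and BclXL types (12 to 14), and with DESeq2 (14 to 18). Of these libraries, pro-B held miR-1-3p at 18114 RPM, CD8 T cells miR-223-3p at 6557 RPM, and follicular helper T cells miR-199a/199b-3p at 42636 RPM, which are miRNAs of muscle, granulocytes and stroma. The calls of miR-425-5p and miR-23a-3p were lost without CD8 T cells (1.24 and -1.62) and without follicular helper T cells (1.27 and -1.69), and that of miR-421-3p without either of them or pro-B cells (1.26, 1.37 and 1.35). With sorted types only the count was 11, and miR-23a-3p (-1.11), miR-23b-3p (-1.34), miR-27a-3p (-2.66), let-7e-5p (-2.24), miR-191-5p (1.52) and miR-425-5p (1.39) were not called. With the covariate for the axis of replicate differences the count was 6, and miR-27a-3p (-1.53), miR-23a-3p (-1.32), miR-374-5p (1.44), miR-421-3p (1.38) and miR-425-5p (1.35) were not called. With no filter on low values miR-374-5p, miR-421-3p, miR-425-5p, let-7e-5p and miR-23a-3p lost their calls, and with library totals miR-421-3p (1.28) and miR-425-5p (1.19).

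T cells stimulated or polarized in culture (concanavalin A, Th1, Th2, Th17 and induced regulatory cells) were compared with 5 sorted types (thymocytes, naive CD4, CD8, follicular helper and natural regulatory cells). The labels do not separate culture from stimulation. miR-210-3p was higher in culture by 4.92 ± 0.99 (1304 ± 1132 against 25.7 ± 25.5 RPM, adjusted p = 0.022). miR-147-3p was higher by 4.89 ± 1.14, miR-182-5p by 3.73 ± 0.95, miR-183-5p by 3.44 ± 0.79 and the candidate arm 09-002c_537447_chr16_5p by 4.49 ± 0.62. miR-122-5p, the main miRNA of liver, was lower in culture, at 4.58 ± 2.45 against 81.8 ± 48.9 RPM (-4.06 ± 0.68). miR-26a-5p (-2.06 ± 0.48), let-7b-5p (-1.95 ± 0.45) and miR-30c-5p (-1.56 ± 0.37) were lower too. Of the cluster of miR-182, miR-96 and miR-183, which T helper cells express upon activation, 2 of 3 members were higher, or 3 over the list alone. Of the miR-30 family 1 of 5 members was lower, or 4 over the list alone. Both lists passed camera (adjusted p = 0.012 each), and neither did with an estimated correlation (adjusted p = 0.49 each). Of the let-7 family 1 of 9 members was lower, or 2 over the list alone, and of the single immune miRNAs 1 was higher and 1 lower, or 1 and 2. No miR-17~92 or miR-181 member was called by limma in either count.

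The count was 13 features, 6 higher and 7 lower, after a TMM shift of 0.42, and with library totals only the split was 7 to 5. It rested on single types: it was 2 without Th1 or without Th2, 3 without naive CD4, 4 without natural regulatory, 5 without Th17 and 8 without CD8 cells, and 21 without follicular helper (15 higher and 6 lower), 25 without induced regulatory and 25 without thymocytes, while without concanavalin A cells it was 10 higher and 3 lower. The covariate for the axis of replicate differences brought the count to 8. Under it miR-182-5p (3.34), miR-183-5p (3.11), miR-26a-5p (-2.06), let-7b-5p (-1.83) and miR-30c-5p (-1.52) were not called. With no filter on low values only the candidate arm was called. That arm and miR-122-5p kept their calls in each of the 10 fits without 1 type, miR-210-3p lost its call without Th1 (4.63) and without Th2 (4.72), and each other named miRNA lost its call in at least 1 of those fits, with adjusted p from 0.051 to 0.15.

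Whether the change with stimulation differed between B and T cells was tested as an interaction over 17 types. limma called 0 of 283 features, with 35 at an unadjusted p under 0.05. On recovered tags DESeq2 called 12, edgeR 0 and limma-voom 0. The difference was 4.84 ± 1.13 for miR-148a-3p (adjusted p = 0.057), which had a change of 5.33 ± 0.87 in B cells and 0.49 ± 0.72 in T cells. It was 3.21 ± 1.19 for miR-155-5p (adjusted p = 0.28) and -3.24 ± 0.90 for miR-326-3p (adjusted p = 0.065). The Sfmbt2 cluster, with 0 of 4 members called and 4 higher adjusted over the list alone, and the Dlk1-Dio3 cluster, with 0 of 3 called and 3 over the list alone, passed camera (adjusted p = 1.7e-05 and 0.012), but not with an estimated correlation (adjusted p = 0.25 and 0.68). The count was 3 without immature B, 6 without B1, 8 without concanavalin A and 6 without thymocyte libraries. miR-148a-3p passed in those 4 fits (5.26, 5.43, 4.68 and 4.53) and with RLE scaling (4.85) or library totals (5.18), and miR-326-3p without concanavalin A cells (-3.65). These are among 11 calls that named miRNAs gained over all the alternatives.

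Myeloid cells (5 types) were compared with lymphoid cells (21 types). miR-223-3p was at 16172 ± 33820 against 372 ± 1422 RPM (6.47 ± 1.44, adjusted p = 0.0021, 5 of 5 myeloid types above the lymphoid median), and miR-223-5p was higher by 5.42 ± 0.85. miR-221-3p and miR-222-3p, which come from a common transcript, were higher by 3.50 ± 0.84 and 3.58 ± 0.95. miR-146b-3p (4.23 ± 0.45), miR-10a-5p (4.21 ± 1.20), a miRNA of the Hox clusters, and miR-511-3p (3.79 ± 0.95), encoded within the mannose receptor gene Mrc1, were higher as well. Lower in myeloid types were miR-150-5p (80.9 ± 160 against 591 ± 649 RPM, -4.61 ± 1.07), miR-150-3p (-5.30 ± 0.95), miR-342-5p (-3.07 ± 0.72) and miR-1964-3p (-3.33 ± 0.60). The 3 tested members of the cluster from miR-106a to miR-363 were lower, with miR-363-5p at -5.24 ± 0.86, and the same 3 were counted over the list alone. This list passed camera (adjusted p = 0.0020), but not with an estimated correlation (adjusted p = 0.46). Of the related miR-17~92 cluster 2 of 5 members were lower, or 3 over the list alone. The 2 were miR-92a-3p (-3.07 ± 0.83) and miR-17-3p (-1.24 ± 0.42). The call of miR-17-3p was lost without mast cells (-1.17), basophils (-1.04) or macrophages (-1.11). In the miR-99/100 and miR-125 group 3 of 4 members were higher in both counts. No miR-181 member was called by limma in either count. Of the let-7 family let-7e-5p (2.43 ± 0.82) was called by limma, and 0 members over the list alone, and its call was lost without mast cells (2.62), dendritic cells (1.71) or macrophages (1.77).

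Of 282 features 77 were called, 39 higher and 38 lower, with a TMM shift of -0.07, and with library totals only the split was 28 to 37. All myeloid types but neutrophils were cultured, while many lymphoid types were sorted, so lineage and culture are partly mixed. With cultured types only 83 features were called, 32 higher and 51 lower, and 49 of them were shared with the 77. The count was 39 without mast cells (23 higher and 16 lower) and 43 without macrophages (25 and 18), and the split was 39 to 59 with DESeq2, 34 to 20 with limma-voom and 63 to 21 with no filter on low values. The calls of miR-125b-5p (3.58 ± 1.25) and miR-152-3p (3.92 ± 1.33) were lost without macrophages (2.26 and 3.25), dendritic cells (3.67 and 3.84) or mast cells (4.03 and 3.44), and that of miR-92a-3p without macrophages (-2.48). edgeR on recovered tags did not call miR-150-5p (-3.09), miR-1964-3p (-1.87), miR-92a-3p (-1.97), miR-125b-5p (2.00) or miR-152-3p (2.73). The macrophage library also held miR-199a/199b-3p at 40929 RPM and miR-143-3p at 4890 RPM, both of stromal cells.

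All 27 blood cell types were compared with 11 tissues. miR-155-5p was at 656 ± 1063 RPM in blood cells and 4.94 ± 5.82 RPM in tissues (5.00 ± 0.64, adjusted p = 2.0e-08), with 27 of 27 cell types above the tissue median. miR-142-5p, made from a hematopoietic host transcript, was at 11741 ± 7836 against 759 ± 1057 RPM (4.01 ± 0.53), and miR-150-5p and miR-15b-5p were higher by 3.67 ± 1.01 and 3.42 ± 0.63. Lower in blood cells were miR-1-3p of striated muscle (-10.54 ± 1.04), miR-143-3p of smooth muscle and fibroblasts (-8.65 ± 0.90), miR-30a-5p (-6.72 ± 0.64) and miR-126-3p of endothelium (-6.26 ± 0.47), the last of these named after its value was seen. The 5 tested members of the miR-17~92 cluster were higher, with miR-92a-3p at 2.75 ± 0.74, and 6 of 9 single immune miRNAs were higher. All 5 members of the miR-99/100 and miR-125 group were lower, with miR-99a-5p at -6.80 ± 0.70 and miR-125b-5p at -6.49 ± 0.87. The 8 tested members of the Dlk1-Dio3 cluster, an imprinted locus active in embryo and brain, were lower, and so were the 3 tested stromal markers. In each of these lists the same number was called over the list alone. The last 3 lists passed camera (adjusted p = 0.0014, 0.0014 and 0.018), and none did with an estimated correlation (adjusted p = 0.44 each). fry called 15 of the 21 lists. Of the let-7 family let-7b, let-7c and let-7e were lower and let-7i was higher in both counts, and no miR-181 member was called by limma in either. The tags of let-7c were split between near-identical miRNAs in 30 libraries.

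Of 245 features 146 were called, 82 higher and 64 lower in blood cells. The TMM shift was 1.10, with library totals only the split was 126 to 49, and with no filter on low values it was 194 to 204. miR-223-3p was not called (-1.23 ± 1.32), and the salivary gland and skeletal muscle libraries held it at 4692 and 4093 RPM.

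**Figure D2:**
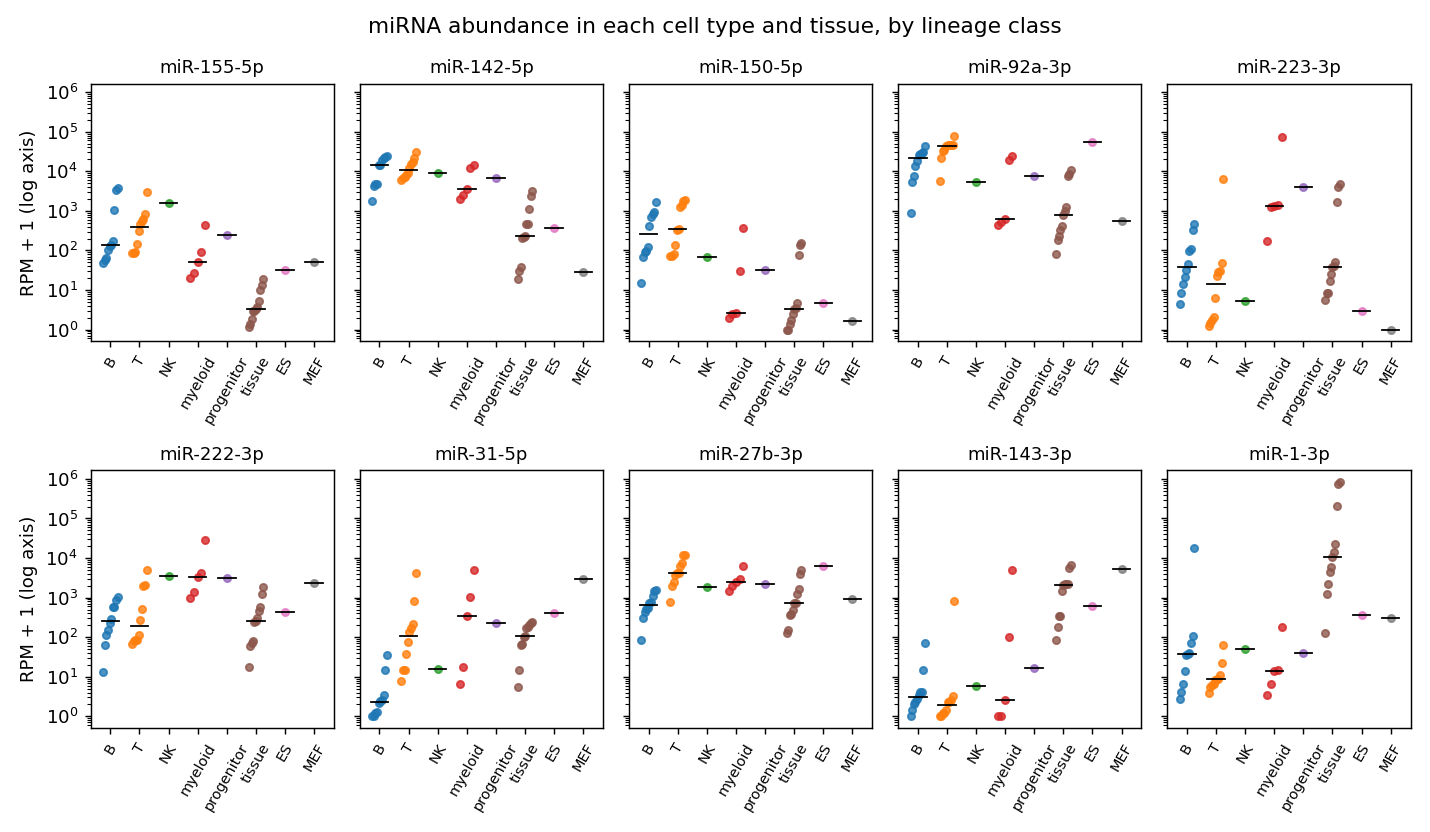
Abundance of 10 miRNAs in each cell type and tissue, by lineage class, as RPM + 1 on a log axis. Each point is 1 type (mean RPM of its libraries) and each bar a class median. All 27 blood cell types lie above the tissue median of miR-155-5p, and pro-B stands apart from the other B types in miR-1-3p at 18114 RPM.

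The following values come from 1 library per type, except where replicates were summed, so no replicate check exists. Folds are ratios of RPM + 1 with the library total as scale. From pre-B to immature B cells miR-150-5p went from 14.3 (95% interval 10.9 to 18.4) to 854 (825 to 883) RPM, 55.8-fold higher, and miR-223-3p was 15.1-fold lower. From immature to mature B cells miR-378-3p was 20.9-fold higher, and miR-92a-3p 9.49-fold, although miR-92a-3p lay at 7149 and 78575 RPM in the 2 mature B libraries. miR-181d-5p was 6.98-fold lower at that step. From pro-B to pre-B cells miR-350-3p was 4.62-fold higher, and miR-206-3p and miR-1-3p were 195-fold and 170-fold lower. Other muscle miRNAs moved with them in this 1 pro-B library, with miR-133a-3p at 78.0 RPM against 1.41 RPM in pre-B cells, and its muscle list lay above all 10000 random lists. B1 cells held miR-375-3p, best known from pancreatic islets, at 629 (605 to 654) RPM, 146-fold above mature B cells, with miR-222-3p and miR-221-3p 24.3-fold and 15.7-fold lower. Plasma cells, from IL-6 transgenic mice, held miR-148a-3p at 12451 (12261 to 12642) RPM, 849-fold above mature B cells, miR-152-3p 368-fold higher, and miR-375-3p at 303 RPM. Marginal zone B cells had miR-139-3p 59.2-fold and miR-139-5p 40.8-fold below mature B cells, with miR-139-3p at 1.70 (0.46 to 4.35) RPM. miR-92a-3p, at 881 RPM in marginal zone B cells, was 56.3-fold below the summed mature B tags (49657 RPM). That fold depends on the mature B library, since these lay at 7149 and 78575 RPM. All 29 features that differed at least 4-fold at this step, at 100 RPM or more in 1 of the 2 types and with separate intervals, were lower. With TMM scaling 1 was higher and 21 lower. let-7f-5p took 48.7% of the marginal zone tags and 22.9% of the mature B tags. The miR-181 list of pro-B cells had a median ratio above 99.8% of random lists, and the miR-17~92 list above 89.5% in pro-B and 84.3% in pre-B cells.

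**Figure D3:**
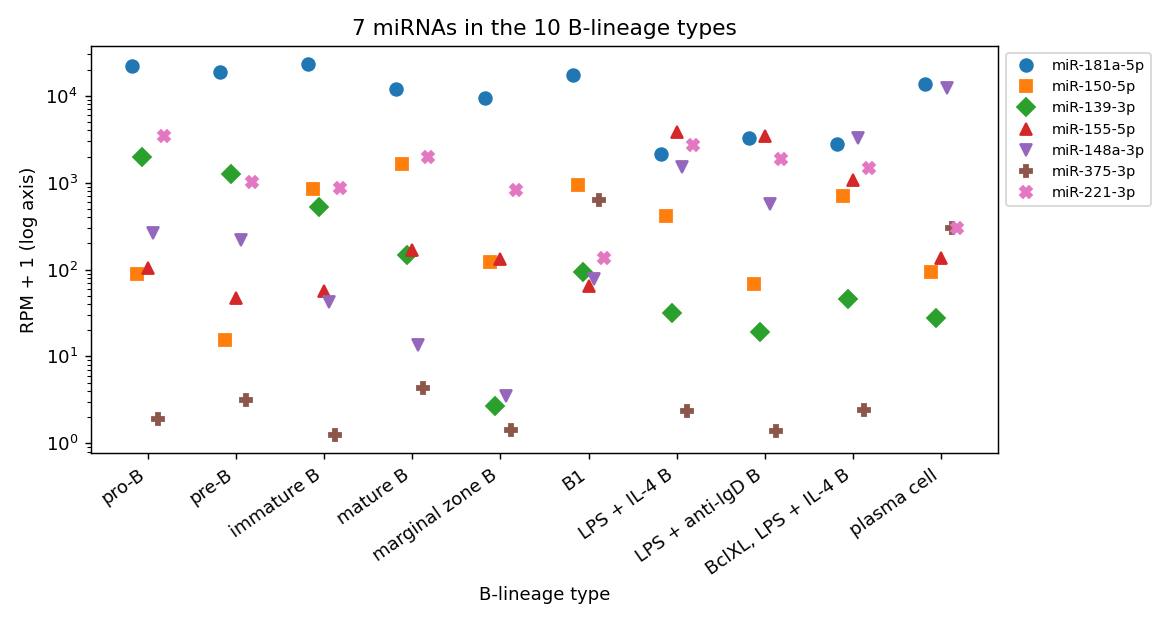
Abundance of 7 miRNAs in the 10 B-lineage types as RPM + 1 on a log axis, 1 point per type and miRNA. miR-148a-3p reaches 12451 RPM in plasma cells, miR-155-5p is highest in the stimulated types, and miR-375-3p stands at 629 RPM in B1 and 303 RPM in plasma cells.

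CD4 and CD8 positive thymocytes were set apart by miR-128-3p at 54136 RPM and by the miR-181 family, with miR-181a-5p at 104086 RPM and a list median above 99.96% of random lists. Natural regulatory T cells held miR-10a-5p at 1519 RPM and miR-146a-5p, a brake on NF-kB signaling, at 1958 RPM, 36.0-fold and 9.00-fold above the median of the other T types. Th1 cells held miR-147-3p at 1103 RPM, and Th17 cells miR-206-3p at 1062 RPM with miR-1-3p at 7.82 RPM. They also held miR-199a/199b-3p of stromal cells at 8759 RPM, 473-fold above the median of the other T types. The stromal list, which does not hold that feature, lay above 98.9% of random lists in Th17 cells. Follicular helper T cells held miR-34c-5p at 23059 RPM and miR-125b-5p at 2817 RPM. Their stromal list lay above 99.95% of random lists. Natural killer cells, cultured with IL-2, held miR-182-5p at 5347 RPM, 355-fold above the median of all other types. Dendritic cells held miR-9-5p, otherwise a brain miRNA, at 2217 RPM, and macrophages miR-199a/199b-3p at 40929 RPM. Progenitors, 60% pure per the labels after 7 days of culture, held miR-223-3p at 4067 RPM, miR-193b-3p at 485 RPM and miR-196b-5p of the Hox clusters at 369 RPM. Mast cells and basophils shared the candidate arm 09-002c_1073496_chr3_5p, at 649 and 665 RPM.

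Embryonic stem cells held the cluster from miR-290 to miR-295, the main miRNA cluster of that state, at 20.9% of tags, with miR-293-3p their most abundant feature at 7.19% (95% interval 7.15 to 7.23). Their let-7 list lay above only 0.25% of random lists. Fibroblasts were led in ratio by miR-143-3p, miR-199a/199b-3p and miR-145-5p, and their Dlk1-Dio3 list (40 members) lay above all 10000 random lists. miR-1-3p took 83.0% (82.9 to 83.0) of the heart tags and 74.5% of the skeletal muscle tags, and miR-122-5p took 67.0% of the liver tags. In testes miR-34c-5p took 44.4% (44.3 to 44.6), and the 16 members of the X-linked testis cluster lay above all random lists. Brain stood apart by miR-124-3p (8724 RPM), miR-9-5p (10275 RPM) and miR-383-5p (7527 RPM), pancreas by miR-217-5p (16176 RPM) and miR-375-3p (45223 RPM), and kidney by miR-196a-5p (1244 RPM) and miR-192-5p (90888 RPM). Skin combined miR-205-5p of epithelium (1651 RPM) with miR-206-3p and miR-1-3p of muscle (14465 and 207669 RPM). Salivary gland held miR-375-3p at 17067 RPM.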

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

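edgeR on recovered tags, pseudocounts of 0.1 and 10 RPM in the comparisons, the covariate for the axis of replicate differences, the omissions of single types from the B against T lineage comparison, and the omission of skin, salivary gland and skeletal muscle were chosen after seeing the data. Over all alternatives, 2952 of 3472 values of named miRNAs kept their direction and their side of the threshold, 271 lost their call, 12 gained one and 1 reversed. The other 236 are values of single libraries that moved by more than their counting interval, with 0 reversed. They are 236 of only 240 such values, taken with TMM scaling or a pseudocount of 10 RPM. Of 120 named values of single libraries, 0 stayed within their interval in both settings, so those intervals do not cover the choice of scale. All 29 named values of blood cells against tissues stayed on their side in every alternative run.

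Counts of called features stayed within 1.5 times the reported count in 129 settings and moved further in 38. With no filter on low values they were 250 for activated against mature B cells, 33 for B against T lineage, 1 for cultured against sorted T types, 23 for activated against resting B types, 4 for the difference in activation and 398 for blood cells against tissues. This setting tests more features, 1619 for activated against mature B cells. DESeq2 called 32, 47 and 74 in B against T lineage, cultured T and activated B types, and 12 in the difference in activation. That difference also gave 4 with RLE scaling, 6 with library totals only, 3 with the stricter filter and 5 with a pseudocount of 10 RPM. With the covariate for the axis of replicate differences, B against T lineage gave 6 and cultured T 8. B against T lineage gave 11 with sorted types only and 26 without other strains, and activated B types gave 24 without the BclXL strain. Camera with an estimated correlation called 0 of the 134 list tests, against 14 at the preset correlation. fry called 6 of 17 lists for activated against mature B cells, 6 of 17 for neutrophils and 4 of 14 for activated B types. It called 2 of 14 for B against T lineage, 2 of 14 for cultured T and 1 of 18 for the difference in activation. For myeloid against lymphoid types it called 2 of 19, and for blood cells against tissues 15 of 21. The cause of these moves was not tested.

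Leaving out 1 library or type at a time gave 117 to 195 calls for activated against mature B cells, 104 to 139 for neutrophils, 13 to 18 for B against T lineage (3 types tried), 2 to 25 for cultured T, 21 to 50 for activated B types, 0 to 8 for the difference in activation and 39 to 82 for myeloid against lymphoid types. miR-92a-3p in activated against mature B cells, at -0.91, was at -2.67 without mature B replicate 1 and reversed to 0.84 without mature B replicate 2. The cause was not tested. Where an omission left 1 library in a group, that library is assumed to vary like the other groups. With the replicate number as a block the counts were 136 for activated B cells and 142 for neutrophils. The numbers are only shared between the groups. Over 305 features the differences between replicates correlated at 0.307 between mature and stimulated B cells and at 0.0944 and 0.0243 between either and neutrophils. Depth limits the single libraries most in testes, where 3 tags stand for 6.69 RPM.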

Other observations

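The tests of depth, of library preparation or animals, of whole skin RNA and of muscle RNA as in skin, and all the splits of the samples, were chosen after the result was seen.

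The replicates of mature B cells and of LPS plus IL-4 stimulated B cells differed along a shared axis, with miR-92a-3p at its end in mature B cells. The depth ratio along the axis was 0.56 on the log2 scale in mature B cells and -0.34 in stimulated B cells, opposite signs that argue against depth as the cause. Over 100 features without split tags the differences of the 2 groups correlated at 0.316 (95% interval 0.10 to 0.504), which leaves open whether splitting of tags between near-identical miRNAs adds to the axis. The correlation over all 109 features at 100 RPM or more, 0.369 (0.154 to 0.542), is the axis itself and does not test library preparation or animals that differ between replicates, which stay open since no label names what these libraries share. Both intervals come from resampling features, with a single replicate difference per group, and do not cover variation between libraries. The sign of the correlations rests on pairing the replicates by number. Over the same 109 features the mature B difference correlated at 0.305 with that between the neutrophil replicates, and the stimulated B difference at 0.114. The axis may thus not be confined to the B cells. No biological explanation was tested.

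The pro-B library held miR-1-3p at 18114 RPM and miR-206-3p at 880 RPM, against 105 and 3.52 RPM in pre-B cells. Heart RNA is argued against, since miR-206-3p lay 12961 times above the level that a share of heart RNA giving this miR-1-3p would bring, and so is whole skin RNA, since 6 epithelial miRNAs of skin lay at a median of -0.0253 times the level needed (-0.528 to 0.0278). Skeletal muscle RNA at a share of 2.43% may be the source, with miR-206-3p at 1.80 times the level needed, the 1 other muscle miRNA above the limit of 1000 RPM, although miR-133a-3p lay 14.2 times above its level. The muscle miRNAs alone, in the proportions of the skin library, lay at a median of 0.697 times the level needed over 3 miRNAs (0.304 to 1.20), at a share of 8.72%. The cells were sorted, which would remove muscle cells, and carry-over between libraries or expression in pro-B cells was not tested.

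The CD8 T library held miR-223-3p at 6557 RPM. Neutrophil RNA at a share of 8.52% may be the source, since 8 other miRNAs of a neutrophil list lay at a median of 1.01 times the level needed (-1.38 to 1.33). Among the 8 is miR-223-5p, at 1.05 times its level. It is the other arm of the hairpin that set the share, so it is not separate evidence of neutrophil RNA. The 2 lowest, miR-1948-3p and miR-34c-5p, have medians in other sorted T types (13.1 and 8.53 RPM) above the levels needed (5.18 and 6.10 RPM), and the list was picked from these libraries as 9 of the 10 largest increases in neutrophils over mature B cells, with miR-148a-3p left out by hand. A change of miR-223 alone is argued against, because 4 of 7 listed miRNAs other than miR-223 lay over 2-fold above the highest other sorted T type. The cells were sorted, which would remove most neutrophils, and expression of the whole set in CD8 T cells was not tested.

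The samples of each comparison over types were also split in other ways, the real split counted among them. Only the real split gave as many called features for B against T lineage (1 of 100 splits, 17 calls against at most 6 in the others), for activated against resting B types (1 of 35, 37 against 13), for myeloid against lymphoid types (1 of 100, 77 against 20) and for blood cells against tissues (1 of 100, 146 against 3). For cultured against sorted T types 2 of 100 splits gave 13 or more, and the other one gave more than the real split, 17. These counts were thus unusual among the splits at the 0.05 level. The splits treat related cell types as interchangeable and were chosen after the result was seen, so they do not exclude chance. For the difference in activation, with 0 calls by limma (35 at an unadjusted p under 0.05, DESeq2 12, edgeR 0 and limma-voom 0), all 100 splits, which gave up to 6, reach as many by construction, so the splits say nothing about chance there.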
